A study of Mus musculus with 16 samples.

How the data were processed

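Left ventricles of 16 AngII-treated mice were sequenced as total RNA. Per the labels' protocols, RNA was extracted with TRIzol and purified with a column kit, and libraries were made with a directional kit. The submitters' processing notes list DRAGEN, DESeq2 and the mm10 build, without saying what each was used for or in which version, and the annotation is not given in the sources used here.

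The deposited count table holds whole counts per gene symbol for each mouse, 24982 entries in all, of which 5760 had 0 counts in every sample. The deposited normalized table holds a signal per gene for the same mice and 16405 genes. That signal equals the counts divided by 1 size factor per sample: after multiplication, 100 percent of its values were whole to within 0.001 and all 16405 genes had the values of the count table. It holds every gene with at least 10 counts summed over the samples, the largest sum left out being 9. No mitochondrially encoded gene was in the count table (0). In 26 entries the gene symbol had become a date, as spreadsheet programs do. For 21 of them the symbol was restored by exact match of their counts to the normalized table, and 5 kept no symbol. Symbols were compared with GENCODE M21 names (24485 matched). Positions are those of whole genes in RefSeq GRCm38.p6 (24417 symbols matched). Symbols alone identify the genes, so reads shared between similar genes, such as the Y-linked genes and their X-linked relatives or members of the C1r, C1s and Serpina3 families, could not be followed. No 2 libraries were duplicates of one another (120 pairs).

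Groups and sexes were taken from the labels. Replicate numbers 1 to 8 within each genotype were assigned here in the order of the records. Before the data were examined, the comparisons, the tests, the gene lists, the rule for named genes and most alternative settings were fixed.

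Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by genotype and sex, which left 13775 genes, and libraries were scaled by TMM. A quasi-likelihood model with genotype and sex as terms tested the genotype and the sex, and a model with 1 mean per genotype and sex tested the genotype within males, within females and the difference between these. p values were adjusted by the Benjamini-Hochberg method and called under 0.05. Log2 fold changes carry an SE worked back from the test, as the absolute log2 fold change over the square root of its F statistic. It is approximate, above all for large changes. CPM are given as mean and SD over mice.

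Gene lists, 36 in number, were tested with camera (limma 3.58.1) at its preset correlation of 0.01 between genes, where at least 5 members were measured, which left 35. The mitochondrially encoded list had 0 members in the table and was not tested. The process lists covered talin and integrin adhesion, fibrillar collagens and matrix glycoproteins, matrix remodelling enzymes, activated fibroblast and myofibroblast markers, the fetal gene programme and hypertrophy, sarcomere, calcium handling and ion channels, fatty acid oxidation, nuclear oxidative phosphorylation, glycolysis, the renin-angiotensin and natriuretic peptide pathway, TGF-beta and SMAD, YAP/TAZ and SRF/MRTF targets, immediate early genes, inflammatory cytokines and chemokines, the interferon response, complement, antigen presentation, the unfolded protein and integrated stress response, oxidative stress and NRF2 targets, the cell cycle, the circadian clock and sex-chromosome genes. The cell type lists held markers of quiescent fibroblasts, endothelium, pericytes and smooth muscle, macrophages, lymphocytes, granulocytes and mast cells, adipocytes, epicardium and mesothelium, glia, atrium and conduction system, skeletal muscle, and erythroid cells and platelets. Some genes stand in several lists. Each list was also tested with a correlation estimated from the data, with fry in 1 direction, and by exact two-sided permutation of the list score between genotypes within each sex, or between sexes within each genotype (4900 exchanges). Fry's mixed test, for members moving either way, was taken up after the data were seen. The permutation was chosen after the data were seen and was not run for the dependence on sex, which no exchange of labels tests exactly.

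The rule for named genes took Tln1 and Tln2 first. It then took up to 12 genes higher and 12 lower by size of change among those that passed at 2 CPM or more (8 and 8 between the sexes and within a sex). Where fewer passed it was topped up to 10 with the genes of lowest p as values that did not pass. It added up to 4 members of lowest p for each described list.

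The alternative settings fixed in advance were DESeq2's size factors, no filter on low counts, a stricter filter (1 CPM in 8 samples), the omission of a covariate, the title number as a covariate, 1 surrogate variable (sva 3.50.0), limma-voom with quality weights, DESeq2 1.42.0, limma on log2 of the deposited normalized values with a pseudocount of 1, each sex fitted alone, an adjusted p threshold of 0.10, and each library left out in turn. Alternatives chosen after the data were seen were the counts recovered from the normalized table, the permutation of list scores, the omission of 4 females with Y-linked reads above 1 percent of the male mean, and the omission of the 2 libraries that stood apart on the leading components or in depth (Tln2-null replicate 8 and knockout replicate 8). Knockout replicate 8 had the lowest total counts. The later search for mice far from their group flagged Tln2-null replicate 8 on the second component. It did not flag knockout replicate 8 for total counts or for the first 2 components. A replicate block was also chosen after the data were seen. Numbers 1 to 16 in the sample titles, of which 7 is absent, run through the 4 combinations of genotype and sex in order, and number 18, knockout replicate 8, does not follow that order. The block took them in sets, 1 to 4, 5 to 8, 9 to 12 and 13 to 18, of 4, 3, 4 and 5 libraries, and was fitted again without number 18. Principal components used 500 genes and log2 CPM with a prior count of 2.

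The edgeR steps were tested on simulated data with 200 changed genes. They recovered 40, 76, 96 and 100 percent of changes of 1.25, 1.5, 2 and 3-fold with 8 against 8 mice, with 9 false calls, and 12, 58, 98 and 100 percent with 4 against 4, with 7 false calls. Simulated genes varied independently of one another, and the changed ones stood at 2 CPM or more. These rates therefore need not hold for the real data. The permutation called 5.25 percent of 400 unchanged scores and 100 percent of shifted ones. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.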

Results

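Bulk RNA sequencing was performed on total RNA from the left ventricle of 16 C57BL/6 mice, 1 library per mouse. All mice received tamoxifen by injection for 5 days and, 2 weeks later, angiotensin II (AngII) from an osmotic pump for 8 weeks, a hormone treatment that raises blood pressure. The 2 groups were Tln2-null mice and Tln2-null mice with deletion of Tln1 in cardiac fibroblasts (CF), called knockout mice here, each with 8 mice (4 males and 4 females). Tln1 and Tln2 encode talins, adaptors that link integrins to the actin cytoskeleton. No mice without AngII and no wild-type mice were among the samples. Total counts per library ran from 11161766 in knockout replicate 8 to 19221673 in knockout replicate 5. The Tln2-null libraries detected 16415 ± 119 genes and the knockout libraries 16306 ± 187 genes (SD, n = 8 each). Between genotypes the median standard error over all genes was 0.09 on the log2 scale, which is the precision that this depth and number of mice allowed. A gene with 0 counts in a library could have had up to 0.156 to 0.269 CPM (counts scaled to a common library total), the level of 3 counts, which covers counting error only. Beside sex and genotype, 874 of 13775 genes went with the number in the sample titles (edgeR, linear term), and 39 with that number in sets of 4, and what the number stands for is not given in the sources used here. The most abundant transcripts were cardiomyocyte genes, led by the myosin gene Myh6 at 20278.3 CPM and the calcium pump gene Atp2a2 at 10983.7 CPM.

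Transcripts of both talin genes were present in all 16 libraries, at similar levels in the 2 genotypes. Tln1 (GRCm38 chromosome 4, 43531513 to 43562583) measured 289.0 ± 20.7 CPM in Tln2-null and 274 ± 31.3 CPM in knockout mice (SD, n = 8 each), a log2 fold change of -0.08 ± 0.07 (SE; edgeR adjusted p = 0.942). Per mouse, Tln2-null replicates 1 to 8 had 298.8, 290.8, 250.7, 286, 287.1, 300.3, 322.4 and 276.2 CPM of Tln1. Knockout replicates 1 to 8 had 274.8, 322.8, 292.8, 288.4, 284.1, 259, 220.9 and 246.1 CPM. Tln2 (chromosome 9, 67217085 to 67634045) measured 66.8 ± 7.25 CPM in Tln2-null and 67.1 ± 2.32 CPM in knockout mice, a log2 fold change of 0.01 ± 0.06 (adjusted p = 0.997), so its transcripts remained abundant in mice labelled null for it. Per mouse, Tln2 stood at 71.79, 74.82, 62.45, 61.19, 66.01, 65.84, 76.84 and 55.57 CPM in Tln2-null replicates 1 to 8. The knockout replicates 1 to 8 had 67.88, 62.39, 67.29, 70.43, 68.78, 66.41, 66.95 and 66.42 CPM of Tln2. Counts cover whole genes in whole tissue, and the deleted exons are not given in the sources used here, so these levels check little of either deletion.

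Comparing the genotypes asks which ventricular transcripts go with loss of Tln1 from fibroblasts in AngII-treated mice labelled Tln2-null. The 10 genes of lowest p at 2 CPM or more in either genotype were lower in the knockout, all but Plau. Cxcl14, which encodes a chemokine (chromosome 13, 56288643 to 56296811), stood at 18.6 ± 5.99 CPM in Tln2-null and 9.1 ± 3.96 CPM in knockout mice (SD, n = 8 each). Its log2 fold change was -1.09 ± 0.17 (SE). Igfbp4, which encodes an insulin-like growth factor binding protein (chromosome 11, 99040005 to 99052655), stood at 126.6 ± 13.8 against 87.7 ± 14.3 CPM (log2 fold change -0.53 ± 0.09). Tcf21, a transcription factor of epicardial and fibroblast lineages (chromosome 10, 22817263 to 22820143), stood at 11.5 ± 2.48 against 6.11 ± 2.16 CPM (-0.93 ± 0.18). Plau, the urokinase plasminogen activator, stood higher, at 8.54 ± 1.82 against 13.6 ± 2.61 CPM (0.67 ± 0.13).

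No gene passed in edgeR (0 of 13775), and the smallest adjusted p, that of Cxcl14, was 0.0717. At an unadjusted p under 0.05 there were 700 genes, 264 higher and 436 lower in the knockout. They were 5.08 percent of the genes tested, about the share that this threshold gives by chance. The 10 genes of lowest p at 2 CPM or more are given as values that did not pass over all genes. Genes below 2 CPM are left out, among them Adcy2, of the second lowest p (-2.69 ± 0.46, adjusted p = 0.107), and Aox3 (1.32 ± 0.27, 0.201). Besides Cxcl14, Igfbp4 (adjusted p = 0.107), Tcf21 and Plau (0.158 each), they were Matn2, which encodes a matrix adaptor, at -0.58 ± 0.11, Ripor3 at -1.21 ± 0.23 and the secreted Wnt inhibitor gene Sfrp1 at -0.87 ± 0.17 on the log2 scale. The others were the protease inhibitor gene Serpina3n at -0.84 ± 0.18, the homeobox gene Hoxd8 at -0.96 ± 0.21 and the complement protease gene C1s1 at -0.28 ± 0.06. The adjusted p of these 6 ran from 0.158 to 0.203. For each of the 10, all 8 knockout mice lay on the same side of the Tln2-null mean. The 10 were picked for low p in this same comparison, so that is no separate support. DESeq2 called 17 genes, 3 higher and 14 lower in the knockout (778 at an unadjusted p under 0.05), and all 10 were among them. The limma-voom fit with quality weights called 11 genes, 8 of the 10 among them. A limma fit of the deposited normalized values called 2 (Cxcl14 and Adcy2). Leaving out knockout replicate 8 gave 7 genes (Tcf21, Igfbp4, Cxcl14, Plau, Matn2, Sfrp1 and Col4a6). Leaving out Tln2-null replicate 1 gave 3 (Aox3, Cxcl14 and Adcy2), and leaving out Tln2-null replicate 4 gave 1 (Cxcl14). Leaving out both knockout replicate 8 and Tln2-null replicate 8 gave 5. These 2 libraries held the clock gene Arntl at 27.14 and 28.42 CPM, against 3.661 to 8.436 CPM in the other 14. They held the clock gene Ciart at 2.857 and 1.909 against 6.035 to 16.44 CPM, and their circadian clock scores were -0.333 and -0.376 against -0.107 to 0.214. Aox3, Adcy2, Col4a6, Arntl and Ciart are named after their values were seen.

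**Figure D1:**
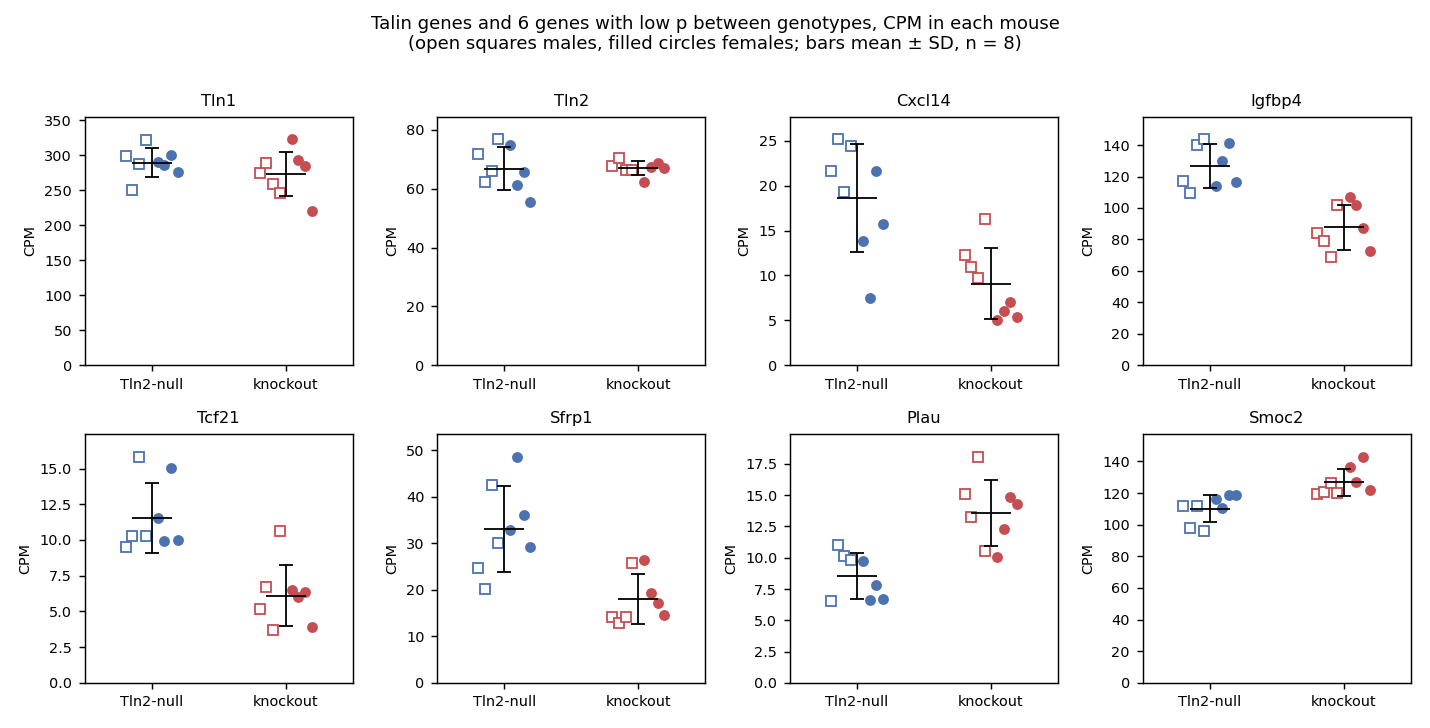
CPM of Tln1, Tln2, Cxcl14, Igfbp4, Tcf21, Sfrp1, Plau and Smoc2 in each mouse, by genotype, with open squares for males, filled circles for females and bars for the mean and SD (n = 8 per genotype). Tln1 and Tln2 overlap between genotypes, while Cxcl14 averages 18.6 CPM in Tln2-null and 9.1 CPM in knockout mice and Plau 8.54 and 13.6 CPM.

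Extracellular matrix and fibroblast gene lists were lower in the knockout. All 30 measured members of the fibrillar collagen and matrix glycoprotein list were lower, with a mean log2 fold change of -0.59 and a median of -0.38. Among them, Fbln1, which encodes the matrix glycoprotein fibulin, stood at 147.9 ± 44.0 CPM in Tln2-null and 87.9 ± 28.2 CPM in knockout mice (SD, n = 8 each; log2 fold change -0.77 ± 0.19). Mfap4, which encodes a microfibril-associated protein, stood at 63.2 ± 38.6 against 26.7 ± 16.4 CPM (-1.25 ± 0.34). Of the activated fibroblast and myofibroblast list, 24 of 25 members were lower (mean -0.76), among them Lox, which encodes a collagen-crosslinking enzyme, at -1.11 ± 0.27, the matricellular gene Thbs4 at -1.37 ± 0.45 and Ltbp2, which encodes a microfibril-binding protein, at -1.61 ± 0.50. Of the quiescent fibroblast list, 18 of 25 were lower (mean -0.19), among them Mgp, which encodes an inhibitor of calcification, at 302.0 ± 99.4 against 192.2 ± 48.8 CPM (-0.66 ± 0.17). Its member Smoc2, which encodes a matricellular protein, lay above the Tln2-null mean in 8 of 8 knockout mice. It stood at 110.2 ± 8.73 CPM in Tln2-null and 126.9 ± 8.50 CPM in knockout mice (0.20 ± 0.05). Of the matrix remodelling enzymes, 24 of 31 were lower (mean -0.27), among them the stromelysin gene Mmp3 at -0.93 ± 0.27 and the Lox relative Loxl1 at -0.53 ± 0.16, while Plau was higher.

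By camera, a set test with a preset correlation between genes, the collagen and matrix list fell (adjusted p = 1.42e-22; adjusted p = 0.128 with an estimated correlation), and so did the activated fibroblast list (2.82e-13; adjusted p = 0.128 with an estimated correlation). The quiescent fibroblast list fell as well (1.46e-08; adjusted p = 0.128 with an estimated correlation), as did the remodelling enzymes (1.74e-07; adjusted p = 0.183 with an estimated correlation). No member passed over all genes tested. Adjusted over the list alone, 10 collagen and matrix members passed, all lower, including Fbln1, Mfap4, Col16a1 and Col8a2, and 10 activated fibroblast members, 9 lower and Fap, which encodes a fibroblast surface protease, higher. In the quiescent fibroblast list 10 passed adjusted over the list alone, 9 lower and Smoc2 higher, and in the remodelling list 6, 5 lower and Plau higher. Exact two-sided permutation of the list scores within each sex gave p = 0.0314 for the collagen list, 0.0376 for the activated fibroblast list, 0.0176 for the quiescent fibroblast list and 0.0224 for the remodelling enzymes, with adjusted p of 0.262 or 0.263. The first principal component was lower on average in the knockout (difference -7.28, exact permutation p = 0.042, adjusted p = 0.147 over 7 library measures). Its largest weights were those of sex-linked genes, such as Xist (0.348) and Ddx3y (-0.275). Members of these same lists, such as Fmod (0.11) and Comp (0.103), also weighed in it, so it gives no separate evidence. The top 10 genes took 7.21 ± 0.257 percent of counts in the knockout against 6.94 ± 0.172 percent (exact permutation p = 0.0278, adjusted p = 0.147). Of single libraries left out, Tln2-null replicate 5 brought the collagen mean nearest to 0 (-0.49). This library held the heat shock genes Hspa1a and Hspa1b at 85.93 and 53.13 CPM, against 2.882 to 8.909 and 1.571 to 5.905 CPM in the other 15. It held the stress response gene Atf3 at 89.6 against 2.669 to 25.1 CPM, all 3 genes named after their values were seen. Without the 4 females that had Y-linked reads above 1 percent of the male mean, 3 of them knockout, 12 of 35 lists were called and the remodelling list was not (mean -0.11, adjusted p = 0.0706). That fit kept 1 knockout female, replicate 2, whose collagen and matrix score (0.647) was the highest of the knockout mice. Changes without these 4 females therefore cannot be tied to the Y-linked reads.

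**Figure D2:**
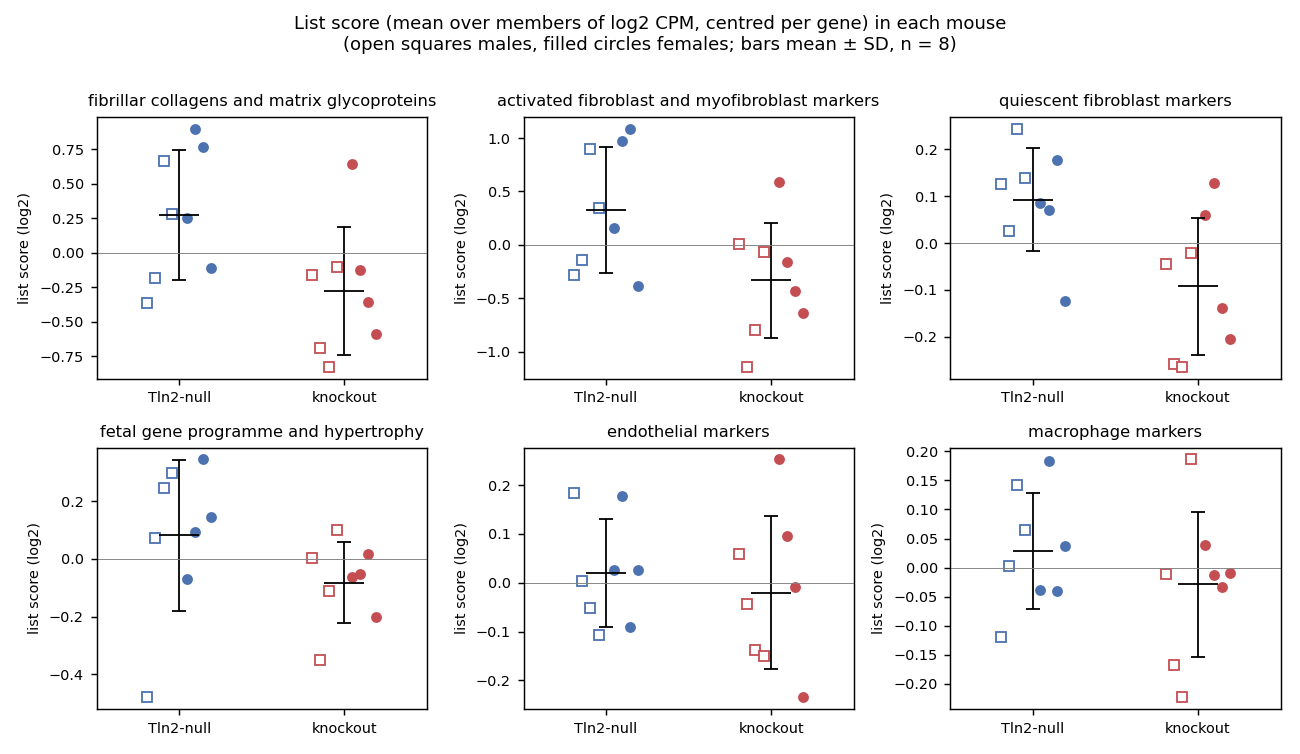
List score of each mouse, the mean over a list's members of log2 CPM centred per gene, for 6 lists by genotype, with open squares for males, filled circles for females and bars for the mean and SD (n = 8 per genotype). The collagen and matrix and the fibroblast lists average lower in the knockout mice, with overlap, and the endothelial and macrophage lists overlap throughout.

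Lists of growth factor signalling, complement and hypertrophy genes were also lower. Of the TGF-beta and SMAD list, 24 of 31 members were lower (mean log2 fold change -0.19, adjusted p = 2.94e-05; adjusted p = 0.183 with an estimated correlation). The ligand genes Tgfb3 and Tgfb2 stood at 35.3 ± 6.80 against 25.8 ± 5.62 CPM (-0.45 ± 0.14) and at -0.38 ± 0.13. None passed adjusted over the list alone (0 of 31; edgeR, 7 at an unadjusted p under 0.05). Of the complement list, 15 of 19 were lower (mean -0.13, adjusted p = 2.94e-05; adjusted p = 0.183 with an estimated correlation), and adjusted over the list alone 5 passed, Serping1, C1ra and C1s1 among them. Serping1, which encodes the C1 inhibitor, stood at 159.4 ± 21.7 against 125.4 ± 18 CPM (-0.35 ± 0.09). Of the fetal gene and hypertrophy list, 24 of 27 were lower (mean -0.21, adjusted p = 0.000125; adjusted p = 0.237 with an estimated correlation). Among them Flnc, which encodes the actin crosslinker filamin C, stood at 693.0 ± 107.6 against 576.1 ± 57.7 CPM (-0.27 ± 0.09). Of the talin and integrin adhesion list, 22 of 28 were lower (mean -0.09, adjusted p = 0.00227; adjusted p = 0.428 with an estimated correlation). The focal adhesion genes Tns3 and Zyx stood at -0.27 ± 0.09 and -0.23 ± 0.10. Neither of the last 2 lists had a member that passed adjusted over the list alone. Exact permutation of the list scores gave p = 0.0469 for TGF-beta, 0.172 for complement, 0.158 for hypertrophy and 0.0882 for adhesion. The adjusted p were 0.274, 0.463, 0.46 and 0.441. Without Tln2-null replicate 1 the mean of the hypertrophy list was -0.32, and without the females with Y-linked reads that of the adhesion list was -0.01 (adjusted p = 0.967).

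Some lists were higher in the knockout. Of the calcium handling and ion channel list, 23 of 32 members were higher (mean log2 fold change 0.05, adjusted p = 0.0019; adjusted p = 0.416 with an estimated correlation). The calcium pump gene Atp2a2 stood at 0.12 ± 0.05, the calcium release channel gene Ryr2 at 0.15 ± 0.06 and the pump inhibitor gene Pln at 0.16 ± 0.07. Of the sex-chromosome list, 11 of 13 were higher (mean 0.13, adjusted p = 0.00518; adjusted p = 0.128 with an estimated correlation), and of the 4 females with Y-linked reads 3 were knockout. No member of either list passed adjusted over the list alone. Exact permutation of the list scores gave p = 0.317 for calcium handling and 0.234 for the sex-chromosome list (adjusted p = 0.525 each). The calcium handling call ended with the title number as a covariate (adjusted p = 0.125), with 1 surrogate variable (mean -0.01, adjusted p = 0.23) and without the females with Y-linked reads (0.053). Its mean was 0.08 without knockout replicate 2 or Tln2-null replicate 8 and 0.02 without knockout replicate 7. The sex-chromosome call ended without the sex covariate (adjusted p = 0.393) and without those females (0.0706).

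In all, camera called 20 of 35 lists, 15 lower and 5 higher. With an estimated correlation 0 were called (9 at an unadjusted p under 0.05), by fry's test in 1 direction 0, and by exact permutation 0 (6 at an unadjusted p under 0.05). With random splits of the same mice within each sex, a test chosen after the results were seen, camera called a median of 11 lists, and at least 1 list in 98 splits, so a call with the preset correlation alone is weak evidence. Fry's mixed test, which counts members moving either way and was also taken up after the results were seen, called 5 lists. These were the quiescent fibroblast (adjusted p = 0.00264), atrial and conduction (0.015), remodelling (0.0232), complement (0.0232) and inflammatory lists (0.0321). The calls of the 10 lists above held without each library in turn, and those of 10 more ended without at least 1. These were higher for fatty acid oxidation (25 of 32 members, adjusted p = 0.000426), nuclear oxidative phosphorylation (31 of 35, 0.00197) and sarcomere genes (19 of 25, 0.0126), with adjusted p of 0.521, 0.597 and 0.594 with an estimated correlation. They were lower for the cell cycle (31 of 33, 0.00189), YAP/TAZ and SRF/MRTF targets (21 of 29, 0.00272), inflammatory cytokines (19 of 25, 0.0126), the interferon response (28 of 34, 0.0126) and pericyte and smooth muscle markers (15 of 21, 0.0142), with adjusted p of 0.597, 0.354, 0.451, 0.597 and 0.518 with an estimated correlation. Atrial and conduction markers (11 of 16, 0.0163) and glial markers (11 of 15, 0.0251) were lower as well, with adjusted p of 0.128 and 0.183 with an estimated correlation. Adjusted over the list alone, Cxcl14 passed in the inflammatory list, Prx in the glial list and Smoc2, Shox2 and Dkk3 in the atrial list, of which Smoc2 was higher. The cell cycle mean was -0.24 with all libraries, 0.04 (adjusted p = 0.664) without Tln2-null replicate 4 and -0.12 (0.124) without knockout replicate 5. Without the females with Y-linked reads the cell cycle list was called in the other direction (mean 0.25, adjusted p = 0.00337), and the inflammatory, interferon and fatty acid oxidation means were 0.02, 0.05 and -0.08 (0.741, 0.122 and 0.873). That fit kept 1 knockout female, replicate 2, with the highest cell cycle score of the knockout mice (0.861). It dropped Tln2-null replicate 4, with the highest of all mice (1.29). The fatty acid oxidation mean was 0.03 with all libraries, -0.02 (adjusted p = 0.0601) without knockout replicate 5 and -0.01 (0.0276) without Tln2-null replicate 4. The list of oxidative phosphorylation had 0.0854, 0.0629 and 0.0584 without Tln2-null replicate 1, knockout replicate 5 and Tln2-null replicate 7. Sarcomere genes had 0.169, 0.113, 0.0614 and 0.0517 without Tln2-null replicate 1 and knockout replicates 5, 6 and 7, and YAP/TAZ and SRF/MRTF targets 0.0766 without Tln2-null replicate 8. Inflammatory cytokines had 0.0688, 0.0834 and 0.309 without knockout replicates 3 and 5 and Tln2-null replicate 8. The interferon list had 0.252 and 0.0861 without Tln2-null replicates 2 and 5, and 0.11, 0.175 and 0.0517 without knockout replicates 3, 5 and 7. Pericyte and smooth muscle markers had 0.154 and 0.157 without Tln2-null replicates 1 and 8, and 0.123 and 0.117 without knockout replicates 6 and 7. Glial markers had 0.0662, 0.151 and 0.148 without Tln2-null replicates 1, 2 and 8, and 0.0606, 0.0657 and 0.0688 without knockout replicates 1, 2 and 3, and atrial markers had 0.0577 without knockout replicate 1.

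**Figure D3:**
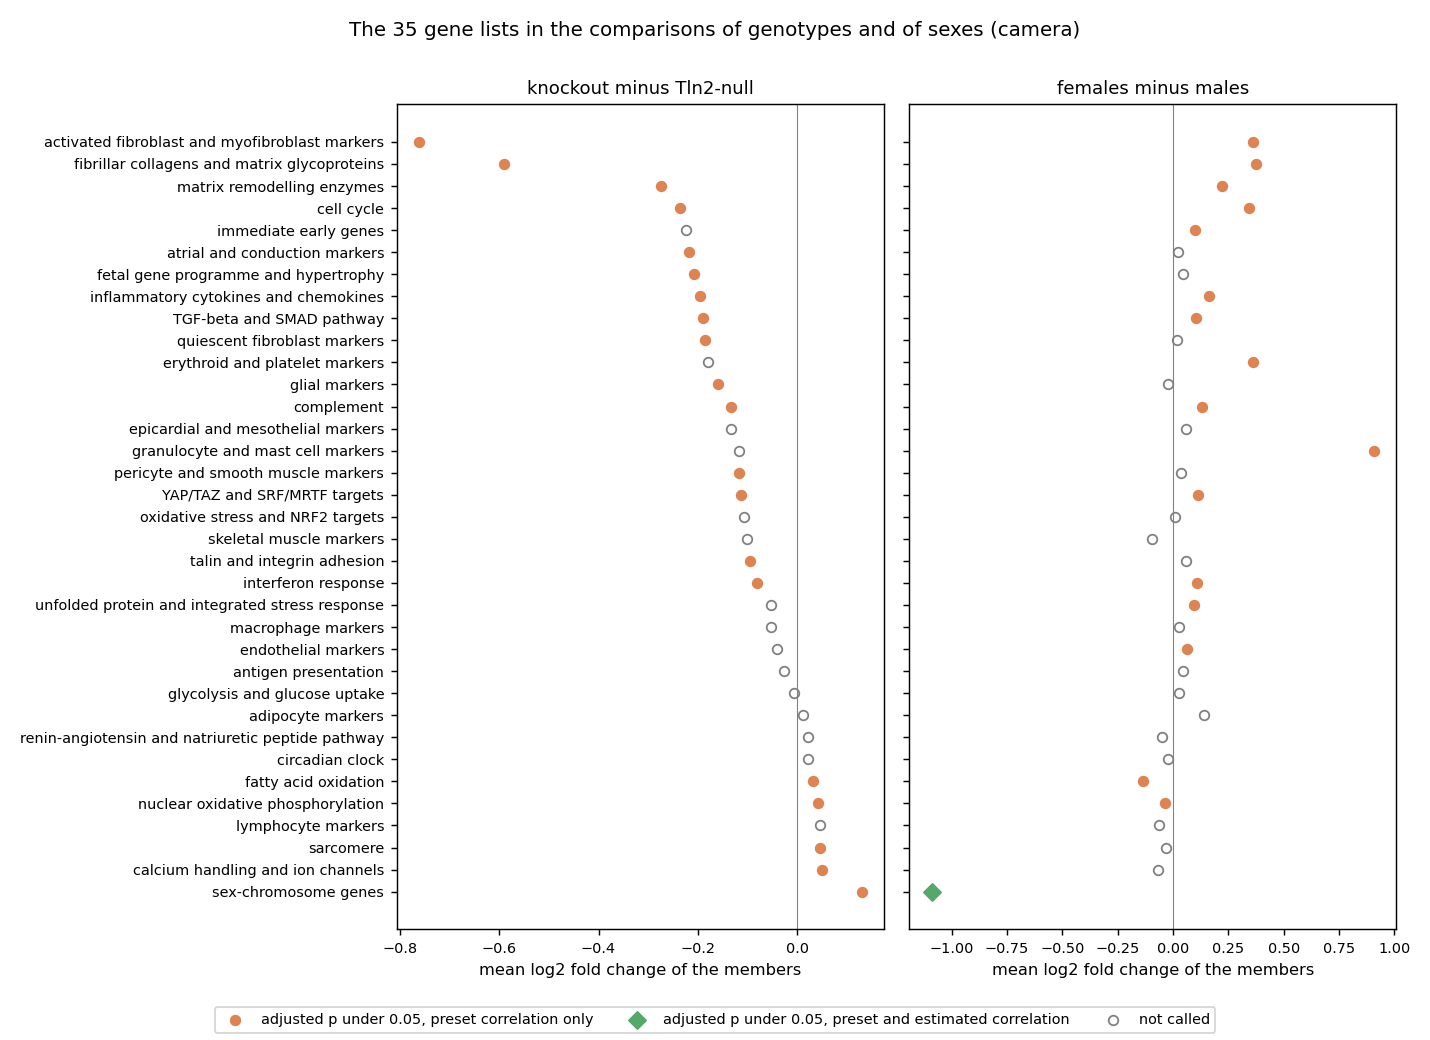
Mean log2 fold change of each of 35 gene lists between genotypes (knockout over Tln2-null) and between sexes (female over male). Orange marks an adjusted p under 0.05 by camera with its preset correlation, a green diamond an adjusted p under 0.05 with an estimated correlation too, and an open symbol neither. The collagen and matrix list lies at -0.59 between genotypes and 0.38 between sexes, and the sex-chromosome list alone has a green diamond.

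Comparing the sexes, across genotypes, asks which ventricular genes differ between male and female mice under AngII. The 12 genes edgeR called lay on the sex chromosomes. Xist, the RNA that silences an X chromosome, was higher in females (318.8 ± 41.2 against 1.68 ± 1.65 CPM in males, SD, n = 8 each; log2 fold change 7.53 ± 0.38, adjusted p = 3.94e-10). The X-linked genes Kdm5c and Kdm6a, which encode histone demethylases, rose by 0.77 ± 0.06 (1.2e-06) and 0.71 ± 0.07 (3.04e-05). The translation factor gene Eif2s3x and the RNA helicase gene Ddx3x rose by 0.66 ± 0.04 (1.67e-08) and 0.54 ± 0.05 (2.26e-05). Pbdc1 (0.69 ± 0.08, 0.000206), the ubiquitin ligase adaptor gene Asb11 (0.26 ± 0.05, 0.0438) and Jpx, an RNA gene below the 2 CPM of the naming rule and named after its values were seen, were also higher. The Y-linked relatives of these genes were lower in females, namely Uty at -6.77 ± 0.21 (2.7e-13), Kdm5d at -6.59 ± 0.29 (8.91e-11), Ddx3y at -6.53 ± 0.33 (3.94e-10) and Eif2s3y at -6.30 ± 0.31 (3.83e-10). Without the females with Y-linked reads above 1 percent of the male mean these were -7.82, -8.93, -8.58 and -8.14, so the size of these differences depends on those libraries. These 12 genes, 8 higher and 4 lower, were those edgeR called of 13775 (508, or 3.69 percent, at an unadjusted p under 0.05). For each named one all 8 females lay on one side of the male mean. DESeq2 called 21, 10 higher and 11 lower, with Hsd11b1, Cxcl14, Cpxm2, Penk and Cnmd, which lie on other chromosomes, lower in females. Of these, Hsd11b1, which encodes a steroid dehydrogenase, was at -0.71 ± 0.14 in edgeR (adjusted p = 0.0999). It was called by DESeq2 (0.00166), by limma-voom (0.0429), with the title number as a covariate (0.0362) and with 1 surrogate variable (0.0302). Hsd11b1, Cpxm2, Penk and Cnmd are named after their values were seen. In all 30 settings 10 of the 12 were called, but Jpx in 12 and Asb11 in 11 of 30. The call of Asb11 ended without each of 12 libraries (Tln2-null replicates 2, 3, 4, 5, 7 and 8 and knockout replicates 2, 4, 5, 6, 7 and 8; adjusted p from 0.0738 to 0.14), and its adjusted p without the females with Y-linked reads was 0.519. Tln1 (0.03 ± 0.07) and Tln2 (-0.07 ± 0.06) did not pass (adjusted p of 1 each).

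Beyond the sex chromosomes, matrix and granulocyte lists were higher in females. All 30 members of the collagen and matrix list were higher (mean log2 fold change 0.38, adjusted p = 5.25e-10; adjusted p = 0.457 with an estimated correlation). The collagen gene Col14a1 stood at 44.6 ± 16.6 CPM in females and 26.9 ± 13.5 in males (0.76 ± 0.24) and the proteoglycan gene Bgn at 0.31 ± 0.14. The remodelling list (24 of 31 higher, mean 0.22, adjusted p = 0.000109; adjusted p = 0.457 with an estimated correlation) included the gelatinase gene Mmp9 at 1.01 ± 0.31. The activated fibroblast list (22 of 25 higher, mean 0.36, adjusted p = 0.000351; adjusted p = 0.596 with an estimated correlation) included the smooth muscle actin gene Acta2 at 0.52 ± 0.22. Without knockout replicate 2 these 3 means were 0.23, 0.15 and 0.22. All 11 granulocyte and mast cell markers were higher (mean 0.91, median 0.41, adjusted p = 4.65e-07; adjusted p = 0.457 with an estimated correlation), led by the calprotectin genes S100a8 and S100a9. These stood at 10.3 ± 8.29 against 2.82 ± 1.40 CPM (1.86 ± 0.46, adjusted p = 0.407) and at 14.2 ± 11.2 against 4.31 ± 2.52 CPM (1.70 ± 0.47). Adjusted over the list alone 5 granulocyte markers passed, S100a8, S100a9, Retnlg, Mmp8 and Cxcr2, and none of the collagen, remodelling or activated fibroblast members. Without Tln2-null replicate 6, S100a8 passed over all genes (adjusted p = 0.0455), as did Cxcl14 (-0.97, 0.00698), which with all libraries was at -0.82 ± 0.17 (0.122). The granulocyte mean was 1.38, 1.42, 1.49, 1.42, 1.37 and 1.38 without Tln2-null replicates 1, 2 and 6 and knockout replicates 3, 6 and 8. The low-count filter was run again in each of these fits, so the members tested could differ from the 11 above. These means therefore do not show the effect of the omitted mouse alone. Complement genes were higher for 15 of 19 (mean 0.13, adjusted p = 0.000318; adjusted p = 0.457 with an estimated correlation), and adjusted over the list alone the complement regulator gene Cd55 (0.37 ± 0.11) and the membrane attack component gene C7 (-0.78 ± 0.21) passed. Exact permutation of the list scores gave p = 0.141 for collagen, 0.0927 for remodelling and 0.312 for activated fibroblast genes. It gave 0.0294 for granulocyte and 0.184 for complement genes, with adjusted p from 0.343 to 0.749 over these lists.

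Fatty acid oxidation genes were lower in females for 30 of 32 (mean -0.14, adjusted p = 7.29e-05; adjusted p = 0.596 with an estimated correlation). Exact permutation of the list score gave p = 0.24 (adjusted p = 0.712). The dehydrogenase gene Acadm stood at -0.12 ± 0.06 and the lipase inhibitor gene Angptl4 at -0.93 ± 0.48, and the list's mean was -0.05 and -0.09 without Tln2-null replicates 1 and 4. For the sex-chromosome list the mean was -1.09, the median 0.54 and the test pointed down (adjusted p = 3.95e-13; adjusted p = 6.11e-05 with an estimated correlation), 12 of 13 members passing adjusted over the list alone. The immediate early (20 of 25, adjusted p = 0.00237), YAP/TAZ and SRF/MRTF target (25 of 29, 0.00171), stress response (23 of 29, 0.00231) and erythroid and platelet lists (8 of 9, 0.00417) were higher, with adjusted p of 0.596, 0.457, 0.457 and 0.457 with an estimated correlation. Camera called 17 of 35 lists, 14 higher and 3 lower in females, against a median of 12 in random splits, but 1 list, the sex-chromosome genes, with an estimated correlation, by fry in 1 direction and by exact permutation (p = 0.000408, the smallest these permutations can give, adjusted p = 0.0143). Fry's mixed test called 3, the sex-chromosome (adjusted p = 3.42e-13), quiescent fibroblast (0.0357) and complement lists (0.0489). Without knockout replicate 2 camera called 11 lists. The calls of 6 lists ended without at least 1 library, that of oxidative phosphorylation (34 of 35 lower), TGF-beta (25 of 31 higher), cell cycle (30 of 33), endothelial (21 of 25), interferon (27 of 34) and inflammatory genes (20 of 25). Without knockout replicate 2 their adjusted p were 0.818, 0.313, 0.41, 0.41, 0.674 and 0.231, against 0.0138, 0.0161, 0.00272, 0.023, 0.0233 and 0.0456 with all libraries. In the same order, 0.746, 0.596, 0.738, 0.738, 0.738 and 0.738 were the adjusted p with an estimated correlation. The other libraries whose absence ended a call were Tln2-null replicates 3 (0.0928) and 5 (0.139) and knockout replicate 4 (0.14) for oxidative phosphorylation, knockout replicates 3 (0.0709) and 6 (0.079) for TGF-beta and Tln2-null replicate 4 (0.786) for the cell cycle. For endothelial markers they were Tln2-null replicates 4 (0.138) and 7 (0.085) and knockout replicates 3, 6 and 8 (0.0877, 0.0863 and 0.1). For the interferon list they were Tln2-null replicates 1, 2 and 3 (0.139, 0.362 and 0.162) and knockout replicate 4 (0.0667). For inflammatory genes they were Tln2-null replicates 1, 3, 4, 7 and 8 (0.258, 0.0706, 0.203, 0.0645 and 0.382) and knockout replicates 4 and 6 (0.0529 and 0.079).

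Taken within each sex, the genotype comparison used 4 knockout and 4 Tln2-null mice. In males, Igfbp4 stood at 127.7 ± 16.8 CPM in Tln2-null and 83.2 ± 13.8 CPM in knockout mice (SD, n = 4 each; log2 fold change -0.62 ± 0.13). Serpina3n stood at 62.3 ± 8.42 against 31.6 ± 13.2 CPM (-0.98 ± 0.25) and Psat1, which encodes an enzyme of serine synthesis, at 8.33 ± 2.82 against 4.23 ± 1.03 CPM (-0.97 ± 0.23). In females, Cxcl14 stood at 14.7 ± 5.85 against 5.88 ± 0.899 CPM (-1.32 ± 0.24), Tcf21 at 11.6 ± 2.41 against 5.69 ± 1.22 CPM (-1.02 ± 0.26) and the complement gene C7 at 3.81 ± 0.807 against 7.11 ± 2.45 CPM (0.89 ± 0.24). The other male genes of lowest p at 2 CPM or more were Tia1, C1s1, Fstl3, Cxcl14, Matn2, Zbtb20 and Ccdc3, with log2 fold changes from -0.96 to 0.32, and the other female genes Ripor3, Egr3, Adcyap1r1, Plau, Cog2, Vit and Col4a6, from -1.58 to 0.76. All are values that did not pass over all genes. edgeR called 0 genes in males (836, or 6.07 percent, at an unadjusted p under 0.05, smallest adjusted p = 0.775) and 0 in females (456, or 3.31 percent, smallest adjusted p = 0.471). In males DESeq2 (871 at an unadjusted p under 0.05), limma-voom and limma on the deposited normalized values called 0 as well. In females DESeq2 called 2, Cxcl14 and Ripor3, and both limma fits 0, a fit of the females alone called 1, Cited2, and without Tln2-null replicate 4 edgeR called 1, Cxcl14. Tln1 was at -0.12 ± 0.10 in males and -0.04 ± 0.10 in females, and Tln2 at -0.03 ± 0.09 and 0.04 ± 0.09.

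Matrix lists were lower in the knockout in both sexes. In males 28 of 30 collagen and matrix genes were lower (mean log2 fold change -0.64, adjusted p = 5.41e-10; adjusted p = 0.514 with an estimated correlation) and in females 29 of 30 (-0.57, 7.45e-14; adjusted p = 0.294 with an estimated correlation). Activated fibroblast genes were lower for 23 of 25 in males (-0.78, adjusted p = 6.48e-07; adjusted p = 0.48 with an estimated correlation) and 22 of 25 in females (-0.74, 1.74e-07; adjusted p = 0.295 with an estimated correlation). In males the quiescent fibroblast list (19 of 25 lower, -0.28, adjusted p = 8.26e-09; adjusted p = 0.439 with an estimated correlation) fell. The oxidative stress and NRF2 list (21 of 29 lower, -0.28, adjusted p = 0.000381; adjusted p = 0.457 with an estimated correlation) fell too. The calcium handling list was higher as a group (29 of 32, 0.14, adjusted p = 2.03e-05; adjusted p = 0.457 with an estimated correlation), and 0 of its members passed adjusted over the list alone. In females the lists of immediate early (22 of 25 lower, -0.37, adjusted p = 7.77e-07; adjusted p = 0.283 with an estimated correlation) and inflammatory (21 of 25, -0.40, adjusted p = 1.07e-05; adjusted p = 0.283 with an estimated correlation) genes fell. So did antigen presentation (16 of 17, -0.23, adjusted p = 2.95e-05; adjusted p = 0.337 with an estimated correlation). Camera called 12 lists in males and 16 in females, and 0 in either with an estimated correlation. In males the collagen and activated fibroblast means were -0.40 and -0.46 without Tln2-null replicate 5. With 1 surrogate variable the collagen and calcium calls ended (adjusted p = 0.0984 and 0.213). In females, the collagen, activated fibroblast, immediate early and antigen presentation means were -0.92, -1.11, -0.55 and -0.39 without knockout replicate 2. The immediate early, inflammatory and antigen presentation means were -0.22, -0.25 and -0.12 without Tln2-null replicate 8. Without the 4 females that had Y-linked reads, 1 knockout female, replicate 2, was left, assumed to vary like the other groups, and the collagen mean in females was 0.21 (adjusted p = 0.00083).

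Whether the genotype difference depends on sex was tested as the difference between the females' and the males' log2 fold changes. Malt1, which encodes a protease of immune signalling, went from 18.6 to 22.99 CPM in males and from 21.03 to 16.2 CPM in females (difference -0.67 ± 0.15, SE, 4 mice per group). Psat1 went from 8.33 to 4.23 CPM in males and from 4.56 to 6.24 CPM in females (1.42 ± 0.33). The transcription cofactor gene Cited2 went from 96.5 to 67.2 CPM and from 59.1 to 94.6 CPM (1.20 ± 0.29). The other 7 genes of lowest p, Tia1, Frat1, Ier5, Frmd5, C7, Actg1 and Zfp568, had differences from -1.31 to 1.27. All are values that did not pass over all genes. edgeR called 0 genes (588, or 4.27 percent, at an unadjusted p under 0.05, smallest adjusted p = 0.98), as did DESeq2 (613), limma-voom and limma on the deposited normalized values.

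Immediate early genes had a lower difference in females for 19 of 25 members (mean -0.32, adjusted p = 1.36e-05; adjusted p = 0.589 with an estimated correlation), with the transcription factor genes Egr2 at -2.66 ± 0.78 and Jun at -0.87 ± 0.29. So did 15 of 17 antigen presentation genes (-0.40, adjusted p = 0.000116; adjusted p = 0.589 with an estimated correlation), with the class II genes H2-DMa at -0.80 ± 0.26 and H2-Aa at -0.91 ± 0.38. The difference was lower for 19 of 25 inflammatory genes too (-0.42, adjusted p = 0.00423; adjusted p = 0.589 with an estimated correlation). The oxidative stress and NRF2 list was higher for 24 of 29 (0.34, adjusted p = 0.000333; adjusted p = 0.589 with an estimated correlation), with the heme oxygenase gene Hmox1 at 2.68 ± 0.86 and the catalase gene Cat at 0.42 ± 0.19. No member of these 4 lists passed adjusted over the list alone. Camera called 11 of 35 lists, as many as the median of 11 in random splits, and 6 without knockout replicate 3, and with an estimated correlation and by fry in 1 direction or mixed 0 were called. These splits exchanged the sexes within each genotype, which does not test the dependence on sex exactly. The calls of 7 lists, those of calcium handling, quiescent fibroblast, oxidative phosphorylation, interferon, complement, sarcomere and YAP/TAZ and SRF/MRTF genes, ended without at least 1 library. Without the females with Y-linked reads the immediate early, antigen presentation, NRF2 and inflammatory calls ended. That fit kept 1 knockout female, replicate 2, so the change rests on that mouse. Without Tln2-null replicate 8 the immediate early and inflammatory means were -0.17 and -0.27, and the immediate early mean was -0.19, -0.51 and -0.73 without knockout replicates 1 and 2 and Tln2-null replicate 5.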

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

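The counts over random splits of the samples and the tests of the lower fibroblast and matrix lists were chosen only after the results were seen.

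Fibroblast and matrix lists were lower in the knockout by camera with its preset correlation, but their calls were lost with an estimated correlation (adjusted p from 0.128 to 0.183) and by exact permutation (adjusted p = 0.262 or 0.263). A loss of fibroblasts as the whole cause is argued against by members of the quiescent fibroblast list moving apart once each mouse's mean was removed (exact permutation p = 0.000816). Members also expressed in other cells would fall by less, so this does not settle it. Smoc2 lay above the Tln2-null mean in 8 of 8 knockout mice, but it was picked from that list for its low p and is no separate support. A single library is argued against too, since the collagen and matrix mean nearest 0 with 1 library left out was -0.49, without Tln2-null replicate 5, against -0.59 with all. A lower share of all cells other than cardiomyocytes cannot be told apart from a change within fibroblasts, since the quiescent fibroblast minus endothelial score differed by -0.144 (exact permutation p = 0.0869) and the collagen and matrix minus endothelial score by -0.51 (p = 0.038, adjusted p = 0.0869 over 3 such differences), the latter going against it for the matrix list without settling it. A biological effect of losing Tln1 in fibroblasts stays open and untested, as the whole tissue was sequenced.

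Random splits of the mice show how far chance groupings go. For genes between genotypes the real split called 0, so all 100 of 100 splits gave as many and the count tests nothing about chance. Of the other splits 4 called any gene, the highest 26, which may point to a structure of the samples that was not tested. For genes between sexes the real split called 12 and the highest other 3 (1 of 100 splits, the real one). Exchanged labels mix males and females for Xist and the Y-linked genes, so a lower count was largely fixed in advance. It does not exclude chance for less certain calls such as Jpx and Asb11, made in 12 and 11 of 30 settings. Within males the real split called 0 and the highest other 1 (35 of 35), within females 0 and 4 (35 of 35), and for the dependence on sex 0 and 7 (100 of 100), and these counts of 0 test nothing about chance either. For lists, the real splits called 20 between genotypes, 17 between sexes and 11 for the dependence on sex, against 26, 22 and 21 at the highest of the others (6, 15 and 52 of 100 splits as large), so chance cannot be excluded for any of the 3 counts. The medians of the other splits were 11, 12 and 11 lists, with 98, 99 and 99 of them above 0, so camera with its preset correlation often calls lists where the groups are random. For the dependence on sex the splits exchanged the sexes within each genotype. That also mixes the difference between the sexes, so those counts are a rough guide.

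Genes, scores and library measures were looked at within groups of 4 or 8 mice, 422 sets of values in all, and 34 sets held a mouse far from the others. That is 8.06 percent, where chance gives about 1 in 20, but the same mice recur and many items move together, so the sets are not independent. Knockout replicate 2 stood apart from the other knockout mice for Mfap4 (61.79 CPM), Col8a2 (5.851), Lox (17.25), Thbs4 (66.28), Cdk1 (3.279), the oxidative phosphorylation score (-0.202) and the interferon score (0.359, also among knockout females), and from the knockout females for Hmox1 (61.18 CPM). Tln2-null replicate 4 stood apart from its genotype for Lox (39.9 CPM), Cdk1 (5.435), Serpina3n (93.42) and the cell cycle score (1.29). Tln2-null replicate 8 stood apart on the second principal component (23.01) and, among Tln2-null females, for Zfp568 (68.8 CPM), the immediate early score (0.628) and the NRF2 score (-0.157), and among all females for Mmp9 (5.656 CPM). Within a genotype, Mgp was at 519.1 CPM in Tln2-null replicate 6 and 83.96 in knockout replicate 4, Fhl1 at 805.4 in Tln2-null replicate 7, and Tcf21 at 10.62 in knockout replicate 8. Among females, Tln1 was at 220.9 CPM in knockout replicate 7 and Angptl4 at 24.27 in knockout replicate 5, and among males Mmp8 was at 1.174 in Tln2-null replicate 1. Among Tln2-null females, Col4a6 was at 3.032 CPM in replicate 6 and Cited2 at 51.72 in replicate 2, and among knockout females Clec3b was at 47.78 in replicate 3. Among Tln2-null males, Actg1 was at 116.9 CPM in replicate 1 and Egr2 at 1.221 and H2-DMa at 4.275 in replicate 5, and among knockout males Zfp568 was at 30.76 in replicate 6. Among males, the sex-chromosome score was 0.342 in knockout replicate 8 and the cell cycle score -0.669 in knockout replicate 6.

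The genotype difference depended on sex by camera with its preset correlation for 11 lists, the median of random splits, and for 0 with an estimated correlation. The mean differences, females minus males, were -0.32 for immediate early genes, -0.404 for antigen presentation, 0.341 for oxidative stress and NRF2 targets and -0.419 for inflammatory genes. The other 7 calls ended without at least 1 library, here with the highest adjusted p so reached. They were -0.181 for calcium handling (0.0697 without knockout replicate 2) and 0.182 for quiescent fibroblast markers (0.0742 without Tln2-null replicate 5, with knockout replicates 3 and 4 also ending it at 0.0559 and 0.053). The difference for oxidative phosphorylation was -0.0683 (0.843 without knockout replicate 2, and 0.163, 0.145 and 0.177 without Tln2-null replicate 1, knockout replicate 4 and Tln2-null replicate 7). The interferon difference of -0.158 had 0.236, 0.0622, 0.0722, 0.095 and 0.0969 without Tln2-null replicates 2 and 3 and knockout replicates 3, 5 and 7. The complement difference of 0.221 had 0.142, 0.0559, 0.0674 and 0.091 without knockout replicates 2, 3, 4 and 6 and 0.0738 and 0.0705 without Tln2-null replicates 5 and 6. The sarcomere difference of -0.0608 had 0.774, 0.0559 and 0.178 without knockout replicates 2, 3 and 6 and 0.188 and 0.103 without Tln2-null replicates 1 and 6. The difference for YAP/TAZ and SRF/MRTF targets, -0.105, had adjusted p from 0.0552 to 0.366 without each of 9 libraries (Tln2-null replicates 3, 5, 6 and 8 and knockout replicates 1, 3, 4, 7 and 8).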

How the results depend on the processing

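The counts recovered from the normalized table, the permutation of list scores, fry's mixed test, the replicate block and the omissions of the females with Y-linked reads and of the 2 libraries that stood apart were chosen only after the results were seen. With sets of 4 title numbers as a replicate block, there were 0 genes between genotypes, 11 between sexes and 0 in each other comparison, with 22 lists between genotypes, 14 between sexes and 9 for the dependence on sex. All 127 gene results stayed as they were, while 6 of 58 list results lost their call. These were the TGF-beta, cell cycle and endothelial lists between sexes (adjusted p = 0.0756, 0.0751 and 0.129) and the YAP/TAZ and SRF/MRTF, interferon and complement lists of the dependence on sex (0.072, 0.0618 and 0.072). With that block and without number 18, knockout replicate 8, there were 3 genes between genotypes (Tcf21, Cxcl14 and Matn2), 10 between sexes and 0 in each other comparison, with 25, 16 and 11 lists, and 4 of 58 list results lost their call. With DESeq2's size factors, all 127 gene results and all 58 list results named in the text kept their direction and side of the threshold. For the other settings the cause of a change was not tested. Where libraries were left out, fewer samples were fitted and low-count genes were filtered again, so the members of a list could differ. No preset correlation was used by the estimated correlation, fry or permutation.

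Between genotypes, edgeR's 0 genes became 1 with no filter, 1 with 1 surrogate variable, 1 at a threshold of 0.10, 11 with limma-voom and 17 with DESeq2. They became 2 with limma on the normalized values, 5 without the 2 libraries that stood apart and 0 to 7 with each library left out. DESeq2 gave 21 genes between sexes against 12 and 2 in females against 0, females alone gave 1, and each library left out gave 10 to 14 between sexes and 0 to 1 in females. The 20 lists between genotypes became 0 with an estimated correlation, 0 by fry in 1 direction, 0 by permutation, 12 without the females with Y-linked reads and 14 to 24 with each library left out. The 17 lists between sexes became 1, 1 and 1 by the first 3 of these, 13 with 1 surrogate variable and 11 to 20 with each library left out. The 11 lists of the dependence on sex became 0 with an estimated correlation, 0 by fry in 1 direction, 17 without those females and 6 to 15 with each library left out. Fry's mixed test called 5 lists between genotypes, 3 between sexes and 0 for the dependence on sex.

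Apart from the sex-chromosome list between sexes, the tests that turned were those of the talin genes, at small log2 values, and of lists refitted without the females with Y-linked reads. Tln2 between genotypes (0.01) was -0.041 without those females, -0.019 without the 2 libraries that stood apart and -0.027 to 0.043 with each library left out. Tln1 between sexes was -0.005 with a surrogate variable and -0.007 to 0.071 with each library left out. Tln1 in males was 0.001 and its dependence on sex -0.003 with a surrogate variable. Tln2 in males was -0.072 to 0.022 with each library left out. Tln1 in females was 0.158 without those females and -0.108 to 0.06 with each library left out, Tln2 in females -0.071, -0.015 without the 2 libraries and -0.021 to 0.128 with each library left out, and the dependence of Tln2 on sex -0.041 without those females. Without those females the genotype means were -0.081 for fatty acid oxidation, 0.022 for inflammatory, 0.05 for interferon and 0.247 for cell cycle genes (adjusted p = 0.00337). In females, where 1 knockout mouse was left and assumed to vary like the others, they were 0.215 for collagens (adjusted p = 0.00083), -0.015 for activated fibroblast, -0.022 for immediate early, -0.009 for inflammatory and 0.119 for antigen presentation genes, the tests pointing up. The dependence on sex was 0.061 for YAP/TAZ and SRF/MRTF, -0.041 for inflammatory and 0.158 for interferon genes. The test of the sex-chromosome list between sexes pointed up with no filter (-1.086) and with limma-voom (-1.076), the mean staying negative. A list's mean alone changed sign between genotypes for calcium handling with a surrogate variable (-0.009), fatty acid oxidation without Tln2-null replicate 4 (-0.014) or knockout replicate 5 (-0.018) and the cell cycle without Tln2-null replicate 4 (0.035). For the dependence on sex it did so for sarcomere genes without knockout replicate 2 (0.006), YAP/TAZ and SRF/MRTF targets without the 2 libraries that stood apart (0.004) and immediate early genes without the females with Y-linked reads (0.023).

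Of the 58 list results, 57 lost their call with an estimated correlation and 57 by fry in 1 direction, and by permutation 36 of the 37 it covers. With 1 surrogate variable 14 of 58 lost it, and without the females with Y-linked reads 14 lost it and 12 turned. With each library left out, 837 of 928 list results and 2001 of 2032 gene results stayed as they were. DESeq2 and limma on the normalized values give no list values, and the permutation was not run for the dependence on sex. In simulated data edgeR recovered 40 percent of the smallest changes between 8 and 8 mice and 12 percent between 4 and 4, which limits what small changes the counts above could show. Simulated genes varied independently of one another, so larger changes may be missed in the real data as well.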

Other observations

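The tests of Y-linked reads described here were chosen only after the result was seen.

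Genes of the hypertrophic response in heart muscle, chosen after their values were seen, were lower on average in the knockout but did not pass over all genes. Nppa, which encodes atrial natriuretic peptide, stood at 1060 ± 460.4 CPM in Tln2-null and 788.9 ± 303.6 CPM in knockout mice (SD, n = 8 each; log2 fold change -0.45 ± 0.26, edgeR adjusted p = 0.936). Nppb, which encodes B-type natriuretic peptide, stood at 206 and 187.3 CPM (-0.18), the slow myosin gene Myh7 at 1194 ± 508.7 and 834 ± 235 CPM (-0.51 ± 0.32) and the skeletal actin gene Acta1 at 1594 and 1300 CPM (-0.30). The collagen gene Col1a1 stood at 146.2 and 97.9 CPM (-0.57 ± 0.21, adjusted p = 0.823) and passed adjusted over its list alone.

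The other 15 lists were not called between genotypes. Among cell types, the macrophage (mean log2 fold change -0.05, camera adjusted p = 0.18), endothelial (-0.04, 0.513), epicardial and mesothelial (-0.13, 0.238), lymphocyte (0.04, 0.648), granulocyte and mast cell (-0.12, 0.769), skeletal muscle (-0.10, 0.505), and erythroid and platelet lists (-0.18, 0.0518) did not pass, nor did the adipocyte list, whose mean was 0.01, median -0.04 and test down (0.539). Among processes, the immediate early (-0.22, 0.0988), oxidative stress and NRF2 (-0.11, 0.132), antigen presentation (-0.03, 0.169), unfolded protein and integrated stress response (-0.05, 0.28), circadian clock (0.02, 0.332), and renin-angiotensin and natriuretic peptide lists (0.02, 0.513) did not pass. Glycolysis had a mean of -0.01, a median of 0.01 and a test that pointed up (0.816).

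Libraries of 4 females held Y-linked reads above 1 percent of the male mean of 281 CPM, summed over Ddx3y, Eif2s3y, Kdm5d and Uty: Tln2-null replicate 4 (1.54 percent) and knockout replicates 3 (2.43), 5 (2.85) and 7 (1.1 percent). Against reads of the X-linked relatives, the Y-linked level varied 16.2-fold among females while the relatives varied 1.21-fold. Reads or RNA from male libraries may be the source, since the 4 genes stood in proportions like those of the males, Ddx3y taking 46.4 against 46.5 percent and Uty 8.55 against 12.3 percent (chi-square p = 0.0715). That test takes reads as independent, so it covers counting error only, and it does not show where such reads came in. In the males Xist reached 4.1 CPM, in knockout replicate 1, 1.28 percent of the female mean, and no biological explanation was tested.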
